A study of Xenopus tropicalis with 24 samples.

How the data were processed

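The deposited processed files were used as they are, and no reads were aligned. The ChIP-seq samples are represented by 17 peak lists, and the 4 RNA libraries by 1 table of regions. The 3 input libraries have no list of their own and were not used here. Per the submitters' processing notes, untreated histone libraries were aligned with BWA, and Smad2/3, input and Nodal-inhibited libraries with Bowtie. Peaks were called with MACS2 and annotated with HOMER. Versions and calling parameters are not given in the sources used here. Per the labels, the untreated histone libraries carried multiplexing adapters and the Smad2/3 and inhibited libraries did not, so aligner and adapters go with treatment.

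Per the file headers the peaks were annotated on the xenTro2 assembly, and no xenTro2 sequence was used. Peak positions are deposited as scaffold coordinates, read as 1-based. The score of each peak is the deposited peak caller's score, on a scale that is not stated, and was used only to rank peaks within a list. The distance to the nearest TSS and the nearest gene name are the deposited annotation. The GC content is deposited as a fraction of bases from 0 to 1 and was turned into a percent. Per the file headers the Smad2/3 lists of stages 9 and 10.5 came from stricter calls and the stage 9 list from pooled reads, while the stage 8 list has neither word, so thresholds may differ between stages.

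The RNA table holds deposited raw tag counts per called region, with 46039 regions, of which 20406 name no gene. Per the file headers the regions were called on all tracks together with a bandwidth of 50, a region threshold of 25, a kurtosis threshold of 50, a hit threshold of 90 and strand ignored. The kurtosis score of each region is deposited per the file headers and was not used. Of the per-sample columns in the table, 4 match no listed sample and were not used in any step. The aligner of the RNA tags is not given in the sources used here. Per the file headers the alignments of stages 8 and 9, of stage 10.5 and of the inhibited embryos carry different dates. A batch that follows these dates would go with stage 10.5 and with treatment. Whether the dates mark library batches is not given in the sources used here.

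Tags of regions with the same gene label were summed to 5944 labels, of which 482 name several genes and 158 have regions on several scaffolds. Labels of several genes stayed in the totals and were left out of the gene lists and the named genes. Regions without a gene held 32.6%, 29.1%, 29.5% and 30.5% of the tags at stage 8, stage 9, stage 10.5 and under inhibition, and were left out of the gene comparisons. Named tags came to 4973283, 6659554, 8030203 and 4656275, and all tags to 7383222, 9390029, 11395054 and 6703399, in the same order. Counts were scaled to the named tags of each library (CPM). Ratios are log2 with a pseudocount of 1 CPM, for genes with at least 10 CPM in the higher library of the pair, and a gene counted as changed at 2-fold. Folds are ratios of scaled counts with a conditional binomial (Clopper-Pearson) interval. Where a library had 0 tags the fold is given as a lower bound, with 3 tags put in place of 0. No fold is given where both libraries held at most 3 tags.

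All 24 groups hold 1 sample each, so no test across libraries and no p-value was made. The main comparisons were Nodal-inhibited over untreated stage 9, stage 9 over stage 8 and stage 10.5 over stage 9. Overlap of peaks means at least 1 bp. Shares have Clopper-Pearson intervals. The background of an overlap is the share after moving each peak by 20 to 200 kb within the span of peaks on its scaffold, over 1000 draws (100 for whole histone lists). Peaks that could not be moved within their span were left out of both shares. A promoter peak lies within 1 kb of a TSS. A gene counted as bound, or as having a site, where the annotation names it as the nearest gene of a peak within 50 kb of its TSS. A gene with a peak in that distance but with another TSS closer to the peak did not count. The percentile of a gene list or peak set is its place among 10000 random sets matched on expression decile, on width and score deciles, or, for genes near Smad2/3, on their number of H3K4me1 peaks, and describes these libraries only. A list median needed 3 members.

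The 13 gene lists (Nodal ligands and feedback antagonists, Nodal signal transduction, endoderm, mesoderm, organizer, BMP and ventral, ectoderm and neural, maternal and germ plasm, pluripotency, housekeeping, ribosomal proteins, Hox, and cell types of later stages), the comparisons, the thresholds and the rule for named genes were fixed before the data were examined. That rule takes the 10 largest falls and rises of each RNA comparison, the members of the lists with those changed 2-fold first, the genes nearest to the 10 Smad2/3 peaks of highest score per stage and the 10 widest H3K27me3 peaks of stage 10.5, and list members with a Smad2/3 peak within 50 kb. Some results that this rule takes in are not reported. The nodal1 locus, the recurrent loci, and the sets of zygotic and falling genes were chosen after the values were seen. Zygotic genes are those at least 8-fold higher at stage 10.5 than at stage 8, and falling genes those at least 4-fold lower.

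Alternatives fixed with the plan were TMM and median-of-ratios scaling, pseudocounts of 0.5 and 5, a minimum of 50 CPM or none, the highest region of each gene alone, thresholds of 1.5-fold and 3-fold, distances of 10 and 100 kb, a promoter window of 5 kb, shifts of 200 to 500 kb, the upper part of each list by score, lists brought to equal length or covered length, and overlap of at least 50% of a peak. Alternatives chosen after seeing the data were leaving out the recurrent loci, Smad2/3 peaks of stage 10.5 in place of stage 9, scaling to all regions, genes on 1 scaffold only, and stage 8 in place of stage 9 as the reference.

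The code was tested on simulated data. Of 200 genes changed among 5944, 45.0%, 100% and 100% were recovered at 2-fold, 4-fold and 8-fold in the inhibition comparison, and no unchanged gene was called. The simulated counts held Poisson counting error only, without variation between embryo pools or libraries. They therefore give no rate of false calls for the real comparisons. Overlap counts were checked against bedtools, which gave the same 980 and 5988. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, bedtools 2.31.1, R 4.3.3 and edgeR 4.0.16 (used only for the TMM factors).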

Results

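Whole embryos of the frog Xenopus tropicalis were profiled at Nieuwkoop and Faber stages 8, 9 and 10.5, from the onset of zygotic transcription to the start of gastrulation. Smad2/3, the transcription factors that carry Nodal signals into the nucleus, and 4 histone modifications were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq), each from a pool of 250 embryos. H3K4me1 and H3K27ac mark enhancers and active elements, H3K4me3 marks promoters and H3K27me3 marks Polycomb-repressed chromatin. Transcripts were counted by 3' RNA-seq, which reads the ends of polyadenylated mRNA, from 400 ng of mRNA per library. At stage 9, H3K27ac, H3K4me1 and transcripts were also measured in embryos kept from the 4-cell stage in SB431542, a small molecule that blocks the type I receptors of Nodal and activin. Each of the 24 groups held 1 library, so no difference given here has a replicate check, and all intervals (95%, exact binomial) cover counting error only.

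The called binding sites of Smad2/3 were almost entirely different at each stage. The lists held 207 peaks at stage 8, 865 at stage 9 and 1024 at stage 10.5, with median widths of 243, 324 and 332 bp, and few lay within 1 kb of a transcription start site (TSS): 1.45%, 1.62% and 4.39%. No stage 9 peak overlapped a stage 10.5 peak (upper counting bounds 0.426% of the stage 9 list and 0.360% of the stage 10.5 list). These bounds do not limit how much binding was shared, since calling thresholds may differ between stages. Of the stage 8 peaks, 14 (6.76%, 3.75 to 11.1%) overlapped a stage 10.5 peak and 1 overlapped a stage 9 peak. All 14 lay at 24 recurrent loci (25.7 kb on 22 scaffolds) where an H3K27me3 peak was called at every stage, and none of the other 191 stage 8 peaks was found again at stage 10.5.

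The highest scores of stages 8 and 10.5 belonged to those recurrent loci. The peak with the highest score at stage 8 (375.9) lay on scaffold 43 at 2619644 to 2620804, nearest to mrps30, which encodes a mitochondrial ribosomal protein, and scored 344.7 at stage 10.5. The same locus was among the 10 highest scores at stage 8 for H3K4me3 (489), H3K4me1 (406), H3K27ac (245) and H3K27me3 (284). Other recurrent loci ranked there too, so signal at these loci is not particular to Smad2/3 or to H3K27me3. The next annotated stage 8 peaks were nearest to stk3, a Hippo pathway kinase (scaffold 96, 174905 to 175690, score 306.9), and to LOC100170490 (score 74.6). At stage 10.5 the peaks of highest score outside the recurrent loci were nearest to not, a homeobox gene of the notochord (scaffold 198, 1262284 to 1262959, score 151), and to eef1g, a translation elongation factor (scaffold 782, 348839 to 349380, score 101). At stage 9 they were nearest to efnb3, an ephrin ligand (scaffold 1059, 180241 to 180842, score 34.9, 178081 bp from the TSS), actr3 of the actin-nucleating Arp2/3 complex (31.8), ccdc6, a coiled-coil protein (30.9), per1 of the circadian clock (30.6) and nisch, an integrin-binding protein (26.3). The other 5 of the 10 stage 9 peaks had no annotated gene.

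The stage 9 sites also differed in base composition. Their median GC content was 55.8% (interquartile range 51.6 to 59.1%), against 34.6% (30.9 to 39.7%) at stage 8 and 40.2% (37.6 to 43.4%) at stage 10.5.

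**Figure D1:**
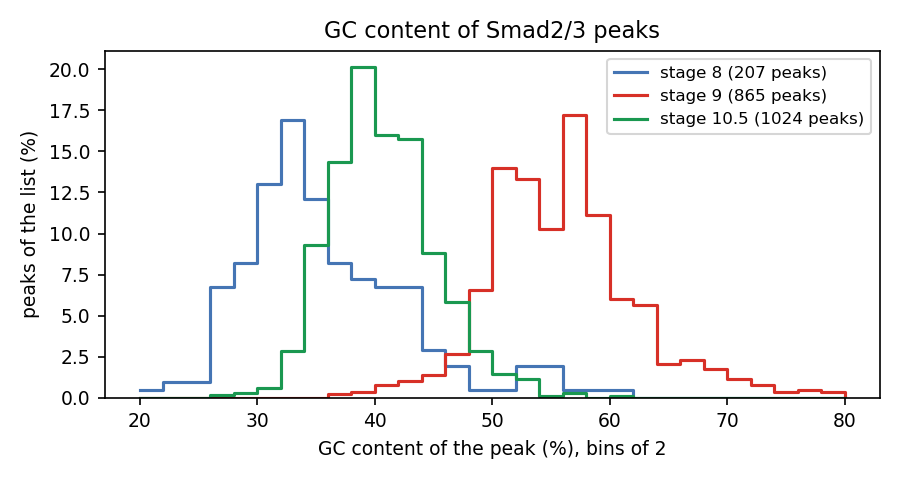
GC content of the called Smad2/3 peaks of stages 8, 9 and 10.5. The stage 9 peaks lie at higher GC than those of the other stages.

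Marks of active chromatin spread as development went on, while called H3K27me3 stayed scarce. H3K4me1 peaks covered 7.53 Mb at stage 8, 59.0 Mb at stage 9 and 92.5 Mb at stage 10.5 (5874, 25975 and 35700 peaks). H3K27ac covered 21.6, 34.6 and 97.1 Mb (8078, 11314 and 23275 peaks), and H3K4me3 covered 1.59, 8.08 and 29.3 Mb (2010, 6839 and 14549 peaks). H3K27me3 peaks numbered 75, 81 and 179 and covered 0.0722, 0.0701 and 0.141 Mb. Sequencing depth of the ChIP libraries, which moves peak numbers, is not given in the sources used here.

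The share of peaks at promoters fell for the enhancer mark H3K4me1, where peaks within 1 kb of a TSS made up 46.4% at stage 8, 17.8% at stage 9 and 12.3% at stage 10.5. Such peaks numbered 2728, 4635 and 4405, so the share fell mostly through peaks added elsewhere. For H3K27ac the shares were 21.7%, 20.0% and 14.9%, and for H3K4me3 34.1%, 47.9% and 32.8%. Most of the length marked at an earlier stage stayed marked at the next for H3K4me1 (94.6% from stage 8 to 9 and 76.1% from stage 9 to 10.5), H3K27ac (72.1% and 77.2%) and H3K4me3 (66.9% and 92.6%). For H3K27me3 the shares were 31.8% and 65.9%, with 32.0% of its stage 8 peaks at the recurrent loci and 73.3% on scaffolds without an annotated TSS. Of its 10 widest peaks at stage 10.5, 6 had no gene, and the others were nearest to ddx39a, an RNA helicase (3492 bp), tom1l1, an endosomal adaptor (3420 bp), psmb1, a proteasome subunit (3208 bp), and oxr1, an oxidation resistance gene (2814 bp), none of them in the fixed gene lists.

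At stage 10.5 nearly all Smad2/3 sites carried enhancer marks. H3K4me1 overlapped 980 of the 1024 sites (95.7%, 94.3 to 96.9%) and H3K27ac 950 (92.8%, 91.0 to 94.3%). H3K4me3 overlapped 303 (29.6%) and H3K27me3 28 (2.73%). Moved to random places on the same scaffolds, the sites that could be moved overlapped H3K4me1 in 14.2% on average (11.1 to 17.7% over 1000 draws, against 97.2% in place) and H3K27ac in 18.1% (15.1 to 21.5%, against 94.9%). The commonest combination was H3K4me1 with H3K27ac and without H3K4me3, at 660 sites (64.5%), while 32 sites (3.13%) carried none of H3K4me1, H3K27ac and H3K4me3. Distal sites kept the pattern, with 98.3% of 919 overlapping H3K4me1 and 95.6% overlapping H3K27ac, and H3K4me3 was found at 86.7% of the 45 promoter sites and 26.7% of the distal ones.

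The sites of the earlier stages mostly lacked marks of their own stage. At stage 9, 779 of 865 sites (90.1%) carried none of these 3 marks, and at stage 8, 179 of 207 (86.5%). H3K4me1 overlapped 57 stage 9 sites (6.59%, 5.03 to 8.45%), and of those that could be moved 6.63% in place and 5.18% on average when moved (2.36 to 8.10%). H3K27ac overlapped 5.43% and H3K4me3 6.13% of the stage 9 sites. Of the movable ones 4.86% overlapped H3K4me3 in place, above every draw of moved sites (mean 1.03%, highest 2.65%), and 4.86% overlapped H3K27ac, equal to the highest draw (mean 2.99%). At stage 8 the shares were 11.1% for H3K4me1, 11.6% for H3K27ac and 11.6% for H3K4me3, and 4.19%, 4.19% and 4.71% of the 191 sites outside the recurrent loci, where only H3K4me3 lay above every draw of moved sites (highest draw 1.65%). Among the 14 promoter sites of stage 9, 57.1% overlapped H3K4me1 and 35.7% overlapped H3K4me3.

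**Figure D2:**
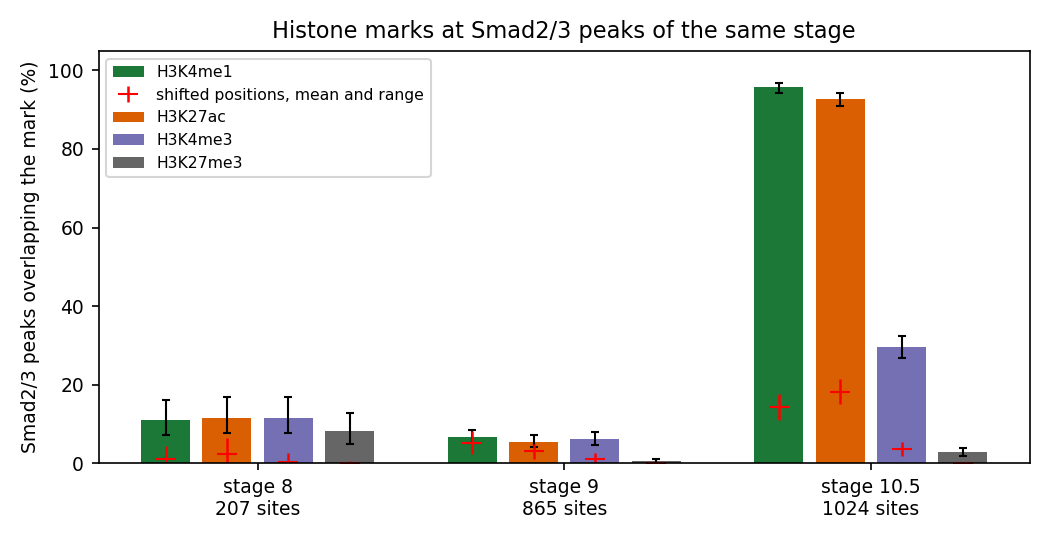
Share of Smad2/3 sites overlapping each histone mark of the same stage, beside sites moved within their scaffolds. H3K4me1 and H3K27ac lie far above the moved sites at stage 10.5 and near them at stage 9, where H3K4me3 lies a few points above.

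The Smad2/3 sites of stage 10.5 lay near the genes that pattern the gastrula. Of 57 genes in the 4 lists of Nodal ligands, endoderm, mesoderm and organizer, 39 had a site within 50 kb (random genes matched on H3K4me1 peaks: mean 4.58, highest 13 of 10000 draws), against 434 of the 8164 genes named in any peak list (5.32%). Where a list entry gave alternative names, the first one found was used. The 57 thus hold nodal but leave out nodal1, and the stage 10.5 sites nearest to nodal1 are not counted. The site of highest score of each of these 39 genes overlapped H3K4me1 at all 39, H3K27ac at 36, H3K4me3 at 10 and H3K27me3 at none. At stage 9, 3 of the 57 genes had a site (random mean 2.09, upper bound of 95% of draws 5), namely foxa2, not and lhx1, and at stage 8 none had.

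By list, a stage 10.5 site lay near 4 of 8 genes for Nodal ligands and feedback antagonists (nodal1 left out), 9 of 14 for endoderm and mesendoderm, 17 of 23 for mesoderm and 12 of 16 for the organizer. The same held for 9 of 14 BMP and ventral genes, 13 of 21 ectoderm and neural genes and 8 of 13 pluripotency genes, each above all random sets. Nodal signal transduction had 2 of 9 (smad3, a Smad of the pathway itself, and tcf7l1, a Wnt pathway repressor), at percentile 88.3 of random sets. Few genes of the other lists had one: 2 of 16 maternal genes (gdf3 and vegt), 1 of 18 housekeeping genes (eef1a1), none of 70 ribosomal protein genes and none of 13 genes of later cell types. Near the latter lists, stage 9 sites were found at gapdh, tubb2b, rpl38, rpl5 and rps3, and stage 8 sites at cpeb1, h2afz and rpl8.

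Among the Nodal feedback genes, a site lay 3.55 kb upstream of lefty, which encodes a secreted Nodal antagonist (scaffold 719, 392731 to 393255, score 56.4). Others lay at cer1, which encodes Cerberus, an antagonist of Nodal, BMP and Wnt (scaffold 443, 3713 to 4120), and at gdf3, a ligand gene of the same list (scaffold 940, 259575 to 260022). Organizer genes with a site included gsc, a homeobox repressor (scaffold 185, 1840116 to 1840484, 0.222 kb upstream), chrd, a BMP antagonist (scaffold 132, 859030 to 859309), foxa4, a forkhead factor with 5 sites (highest score 79.2 on scaffold 474, 91156 to 91595), and otx2, a head homeobox gene (scaffold 68, 1516076 to 1516915). Endoderm and mesoderm genes included eomes, a T-box factor (scaffold 26, 614274 to 614796, 4.65 kb upstream), gata4 (scaffold 63, 2596001 to 2596424) and gata6 (scaffold 84, 2379329 to 2379718) of the endoderm, snai1, a repressor of epithelial genes (scaffold 48, 1048136 to 1048574, score 82.5), vegt, a T-box activator of Nodal ligands (scaffold 12, 4633806 to 4634494, within an intron), and t, the mesodermal T-box factor Brachyury (scaffold 432, 242417 to 242937).

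The chromatin at many of these sites was marked before Smad2/3 was called there. The stage 9 Smad2/3 list shared no peak with that of stage 10.5, so it cannot show that Smad2/3 was absent from these sites at stage 9. Of the 1010 stage 10.5 sites without an earlier Smad2/3 peak, 755 (74.8%, 72.0 to 77.4%) overlapped H3K4me1 at stage 9 and 673 (66.6%, 63.6 to 69.5%) overlapped H3K27ac, and of those that could be moved 76.0% and 67.4% did in place, against 7.46% and 5.18% on average when moved. H3K4me3 overlapped 35 (3.47%) and H3K27me3 8 (0.792%) at that earlier stage. Among the 39 list genes the best site was marked at stage 9 by H3K4me1 at 31 and by H3K27ac at 23. The stage of that H3K27ac list rests on its header, since all its peak names start with a stage 8 prefix. The 864 sites first called at stage 9 were rarely marked at stage 8, with 18 (2.08%) under H3K4me1, 34 (3.94%) under H3K27ac and 29 (3.36%) under H3K4me3. For those that could be moved the shares in place were 0.942, 1.87 and 2.73 points above the mean of moved sites, and above every draw for H3K27ac and H3K4me3.

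Just over 50% of the enhancer-mark peaks of stage 9 were called again under Nodal inhibition. Of 11314 untreated H3K27ac peaks, 5988 (52.9%, 52.0 to 53.8%) overlapped a peak of the inhibited list, and of 25975 H3K4me1 peaks, 13927 (53.6%, 53.0 to 54.2%) did, against 9.13% and 8.68% for moved peaks. In the other direction 40.0% of the 16105 inhibited H3K27ac peaks and 81.6% of the 17162 inhibited H3K4me1 peaks overlapped an untreated peak. The arms also differ in aligner and in sequencing adapters, so loss of a peak cannot be assigned to the inhibitor alone.

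H3K27ac peaks under the called stage 9 Smad2/3 sites were called again less often than matched peaks, and peaks under the later sites more often. Of 46 untreated H3K27ac peaks with a stage 9 Smad2/3 site, 12 (26.1%, 14.3 to 41.1%) were called under inhibition (random peaks matched on width and score: mean 42.9%, percentile 0.68), against 53.0% of those without. The matching leaves out base composition: 23 of the 47 stage 9 sites with H3K27ac had GC of 60% or above, and such GC was found in 2.13% of untreated and 0.317% of inhibited H3K27ac peaks. For H3K4me1 the kept peaks were 21 of 55 (38.2%), within the matched sets (percentile 7.65). With the Smad2/3 sites of stage 10.5, a choice made after seeing the data, 457 of 543 H3K27ac peaks (84.2%, matched mean 75.7%) and 523 of 643 H3K4me1 peaks (81.3%, matched mean 76.5%) were kept. Counted over the 1024 stage 10.5 sites, H3K27ac lay at 684 in untreated and 607 in inhibited embryos, with 161 sites marked only in untreated and 84 only in inhibited embryos. H3K4me1 lay at 757 and 597, with 190 and 30 sites marked in 1 arm only.

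Loci of single genes differed from each other. Only the site of highest score of each gene was compared, and some genes have several, such as foxa4 with 5. At the site of lefty both marks were called in untreated and neither in inhibited embryos, and at the site of snai1 H3K27ac was called in untreated and neither mark in inhibited embryos. The eomes site kept H3K27ac but not H3K4me1. The sites of gsc, foxa4, gata4 and not kept both marks. At the sites of cer1, chrd and otx2, among others, H3K27ac was called in inhibited and not in untreated embryos. Of the 39 genes, 20 had H3K4me1 and 22 had H3K27ac at the site under inhibition, against 31 and 23 in untreated embryos.

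**Figure D3:**
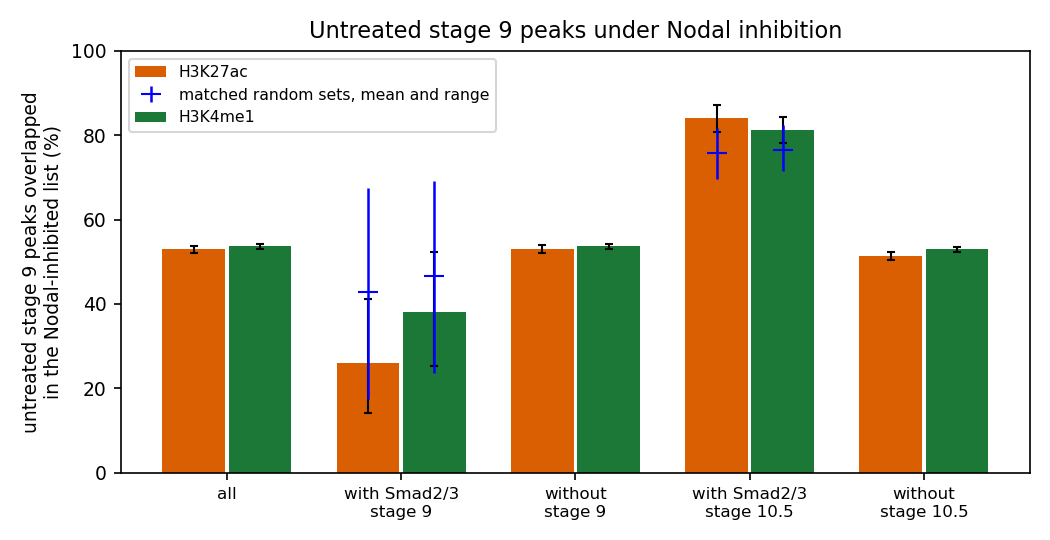
Share of untreated stage 9 H3K27ac and H3K4me1 peaks overlapped under Nodal inhibition, with and without Smad2/3. Peaks under stage 9 Smad2/3 sites lie below, and peaks under stage 10.5 sites above, the share of all peaks.

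The Nodal ligand gene nodal1, chosen after its values were seen, had no H3K27ac peak under inhibition. Within its neighbourhood on scaffold 34 H3K27ac had 1 peak at stage 8, 3 at stage 9, and 3 at stage 10.5. H3K4me1 peaks annotated to nodal1 numbered 4 at stage 9 and 2 under inhibition. Smad2/3 sites of stage 10.5 lay there at 3364181 to 3364667 (score 35.2), 3353570 to 3353908 (29.1) and 3373047 to 3373500 (25.4).

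**Figure D4:**
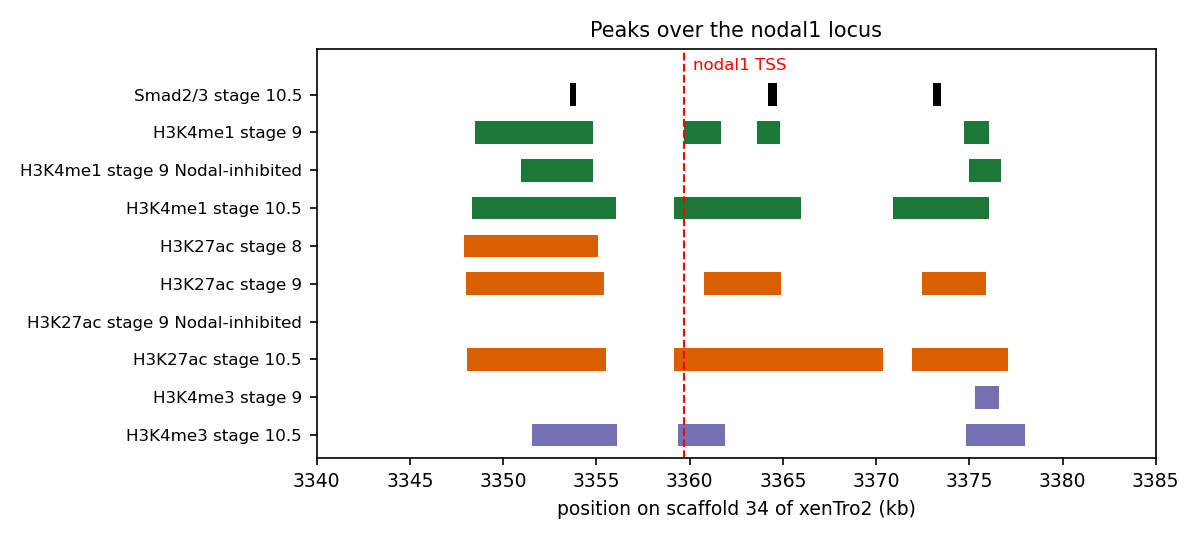
Called peaks around nodal1 on scaffold 34 by mark, stage and treatment. H3K27ac peaks are called there in untreated embryos of every stage and not in the inhibited ones.

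Peaks near genes that were lower under inhibition were called again about as often as others. Of 621 distal H3K27ac peaks nearest to such genes (287 genes), 332 (53.5%) were called again, against 54.5% of all distal peaks (percentile 56.3 of matched sets). For H3K4me1 it was 700 of 1396 (458 genes, 50.1%) against 49.5% (percentile 42.7).

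Transcripts moved in both directions under Nodal inhibition, with genes known as Nodal targets mostly too low at stage 9 to compare. Among 4819 genes, 805 were at least 2-fold lower and 989 at least 2-fold higher in the inhibited than in the untreated stage 9 library, with a median log2 ratio of 0.21. The median was 0.09 with the trimmed mean of M values (TMM) and 0.01 with median of ratios, and the lower share of the changed genes went from 44.9% to 52.0% and 56.9%, so the balance of falls and rises depends on the scaling. The clearest family was that of ribosomal protein genes, whose transcripts were lower: 30 of 65 fell at least 2-fold and none rose, with a median log2 of -0.76 (matched random lists -0.22 to 0.38), -0.88 with TMM and -0.96 with median of ratios. Part of this is set by the reference, since against stage 8 their median was -0.50, -0.11 with TMM and -0.16 with median of ratios, and against stage 10.5 it was -0.93, -0.78 and -0.83.

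The largest falls were those of hadhb, an enzyme of fatty acid oxidation (1961 tags untreated and 0 inhibited, at least 457-fold), rpl27a, a ribosomal protein gene (57.7-fold, 39.8 to 87.0), and mapk8, the stress kinase JNK1 (45.8-fold, 34.9 to 61.2). Next came rpl32, whose regions lie on more than 1 scaffold (370 and 2 tags, 129-fold, 35.6 to 1072), cdc23 of the anaphase-promoting complex (44.2-fold, 32.1 to 62.6), and gyg1, the primer of glycogen synthesis (43429 and 868 tags, a fold between 32.7 and 37.5). They were followed by fn3krp, a kinase that repairs glycated proteins (53.8-fold), fam3c, a secreted protein (35.5-fold), neil3, a DNA glycosylase (155 and 0 tags, at least 36.1-fold), and n6amt2, a methyltransferase (1043 and 27 tags, a fold between 18.5 and 41.2). Several of these were also far higher in the untreated stage 9 library than at stages 8 and 10.5, such as gyg1 with 6521 CPM (library-scaled tags) against 1578 and 589. Within the ribosomal list the falls of rps15a (16.9-fold), rpl4 (10.4-fold), rps16 (10.2-fold), rpl6 (8.91-fold) and rpl36 (8.02-fold) were among the largest.

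The largest rises were those of vamp4, a vesicle fusion protein (1 and 225 tags, 322-fold, 57.2 to 12766), rabggtb, which prenylates Rab proteins (at least 80.6-fold), rad1 of the DNA damage clamp (at least 73.9-fold), and esrrg, an orphan nuclear receptor (at least 60.1-fold). The glutathione transferase gsta4 rose 36.7-fold (23.3 to 61.5), dip2c 166-fold from 1 tag (29.2 to 6609), the gastrula gene gs17 19.2-fold (15.7 to 23.7), the death-signalling kinase ripk1 55.8-fold from 3 tags (18.6 to 274), the scaffold protein gene cnksr2 20.5-fold (14.7 to 29.4) and the chemokine receptor cxcr4, expressed in mesendoderm, 16.1-fold (12.3 to 21.5). Several of these had dipped in the untreated stage 9 library, such as vamp4 with 17.1, 0.150 and 5.35 CPM at stages 8, 9 and 10.5 against 48.3 under inhibition, and gsta4 and cnksr2 were also lower at stage 9 than at both other stages. Among all 989 higher genes the untreated stage 9 value lay at least 2-fold below both neighbouring stages in 305. That is 30.8%, against 11.9% of all genes. The inhibited value lay at least 2-fold above both stages in 119 of the 989, a larger share than the 3.90% of all genes. Among the 805 lower genes the untreated value lay above both in 181 (22.5%, against 4.69% of all genes) and the inhibited value below both in 214 (26.6%, against 8.49%), and choosing genes on this ratio raises all of these shares.

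Genes of the ventral and ectodermal lists mostly rose where they changed, though several could enter the comparison only by rising. The BMP target id3 rose by 3.39 on the log2 scale (a fold between 8.83 and 15.0) and bmp4 itself rose 4.88-fold, with a list median of 0.58 for 5 genes (percentile 76.1). In the ectoderm list the forkhead gene foxi4.2 rose 16.4-fold (8.29 to 36.8) and the keratin gene krt8 3.34-fold (below 2-fold in its highest region alone), while the keratin gene krt18 fell 3.57-fold (median 0.47 for 9 genes, percentile 76.0). The pluripotency list had 1 change, a 10.5-fold rise (7.95 to 14.0) of klf17, a Krüppel-like factor (median 0.25 for 6 genes). Organizer and mesoderm genes that could be compared rose too: admp, an organizer BMP ligand, 13.2-fold (7.99 to 23.2), wnt11, a Wnt ligand of cell movement, 4.55-fold, not 2.54-fold and snai1 2.41-fold (below 2-fold with a pseudocount of 5), with a mesoderm median of 1.32 for 3 genes (percentile 95.1). Of the genes named here, id3, bmp4, foxi4.2, klf17 and admp were under 10 CPM in the untreated library. They passed the minimum through the inhibited library alone, which favours rises.

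Components of the Nodal pathway moved both ways. The transducer smad2 fell 2.44-fold (2.33 to 2.56), the type II receptor gene acvr2b rose 2.36-fold, the Smad partner foxh1 rose 2.03-fold (below 2-fold with the other scalings) and the ligand gdf1 rose 2.34-fold (1.62 to 3.40; below 2-fold with median of ratios). The transduction list had a median of 0.30 for 8 genes (percentile 55.6), and the co-receptor tdgf1 had a log2 ratio of 0.38. The endoderm list had a single comparable gene, vegt, at -0.86 (-1.05 with median of ratios, where vegt counts as lower). Other Nodal targets were below the minimum in both libraries, with 0 and 0 tags for cer1, 1 and 0 for t, 17 and 11 for gsc, 10 and 22 for mix1 and 25 and 39 for sox17b.1, untreated and inhibited. The gene sia1 of the organizer list was below it too, with 3 and 27 tags.

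Of 14 maternal genes 5 fell and 2 rose (median -0.28, percentile 12.2), among them falls of zp2, an egg coat gene (8.86-fold, 5.98 to 13.6), stk11, a polarity kinase (2.89-fold), and kpna7, an oocyte importin (2.73-fold, below 2-fold in its highest region alone), and rises of the germ plasm gene nanos1 (3.43-fold) and the oocyte linker histone h1foo (2.94-fold). Of 17 housekeeping genes 4 fell, gapdh 3.47-fold and ywhaz 3.39-fold most, and 3 rose, hsp90ab1 3.96-fold and tbp 3.69-fold most (median -0.15). No Hox gene passed the minimum, and of the later cell types only alb, the albumin gene, did (0.94).

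Genes near Smad2/3 sites had medians within the range of matched genes under inhibition. The 133 comparable genes with a stage 9 site had a median log2 of 0.24 (matched lists -0.05 to 0.39), with 19 lower and 21 higher. The 209 genes with a stage 10.5 site, chosen after seeing the data, had a median of 0.33 (percentile 93.9), with 33 lower and 61 higher, and 29.2% of them were higher against 20.1% of the other genes.

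From stage 8 to stage 9 the direction of most changes depended on the scaling. Of 4953 genes 1428 were at least 2-fold lower and 361 higher with library totals (median -0.45). With TMM 716 were lower and 850 higher (median 0.08), and with median of ratios 692 and 876 (median 0.10), so the lower share went from 79.8% to 45.7% and 44.1%. Ribosomal protein genes rose under every scaling, with a median of 0.50 (percentile 99.99) and 17 higher and 2 lower, and medians of 1.01 and 1.03 with the other scalings.

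The largest falls from stage 8 to 9 were those of lcp2, an immune adaptor (40.0-fold, 23.6 to 73.8), fam57a, a ceramide synthesis gene (31.4-fold, 18.4 to 58.0), the helicase gene hfm1 (122 and 2 tags, 81.7-fold, 22.1 to 682), esrrg (at least 40.2-fold) and the splicing factor gene rbm9 (29.5-fold). They were followed by the ubiquitin ligase gene mib2 (109 and 3 tags, 48.7-fold, 16.2 to 240), vamp4 (85 and 1, 114-fold, 19.9 to 4548), the chaperone gene chordc1 (22.0-fold), the ephrin gene efna2 (104 and 3, 46.4-fold, 15.5 to 229) and the phospholipase gene pla2g6 (92 and 2, 61.6-fold, 16.6 to 516). The largest rises were those of fam3c (40.0-fold, 28.7 to 57.6), bre of a DNA damage complex (30.5-fold, 16.4 to 64.0), the sialyltransferase genes st6galnac4 (1 and 144 tags, 108-fold, 19.0 to 4277) and st6gal2 (at least 25.1-fold), MGC146893 (21.8-fold), cdc23 (15.9-fold), rpl32 (19.7-fold), gs17 (1 and 103 tags, 76.9-fold, 13.5 to 3067), the zinc finger gene znf3 (at least 20.9-fold) and n6amt2 (14.2-fold).

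In the lists the activin receptor genes acvr2b and acvr2a fell 6.42-fold and 3.12-fold (transduction median -0.57 for 7 genes), and the co-receptor tdgf1 rose by 1.13 on the log2 scale. The growth factor antagonist spry2 fell 4.37-fold and the muscle determinant myf5 3.11-fold, though not with median of ratios (mesoderm median -1.18 for 5 genes), and sall4, a stem cell zinc finger gene, fell by 1.63 on the log2 scale (pluripotency median -1.10 for 5 genes). The BMP list had a median of -0.77 for 4 genes and the ectoderm list -0.59 for 8, with the AP-2 gene tfap2c lower 3.13-fold (below 2-fold in its highest region alone) and krt18 higher 2.74-fold. The maternal median was -0.19, above 0 with the other scalings, and the housekeeping median was -0.52 (percentile 3.77), close to 0 with them.

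Between stages 9 and 10.5 the genes of the germ layers switched on. Every comparable gene of the endoderm (8), mesoderm (17) and organizer (10) lists rose at least 2-fold, with medians of 4.82, 4.68 and 4.96 on the log2 scale, above all matched random lists. Most of these genes passed the minimum through their stage 10.5 value alone, which favours rises. In the inhibition comparison at stage 9 only 1, 3 and 2 genes of these lists passed it. BMP and ventral genes (5 of 8 higher, median 3.95) and ectoderm and neural genes (9 of 14 higher, median 2.22) rose as well. Over all 5045 genes 1465 were higher and 869 lower (median 0.29), and with TMM 1126 and 1130 (median 0.00) and with median of ratios 1083 and 1166 (median -0.02), so that the lower share went from 37.2% to 50.1% and 51.8%. The rises of the germ layer lists hold under each scaling.

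The largest rises were those of cnfn, an epidermal envelope gene (2 and 6304 tags, 2614-fold, 723 to 21589), crx, a homeobox gene of the otx family (at least 1297-fold), krt, a keratin gene (at least 1231-fold), gatm, which makes creatine precursors (at least 594-fold), and id3 (270.0-fold, 212 to 349). The Nodal antagonist cer1, whose regions lie on more than 1 scaffold, rose at least 453-fold, t rose from 1 to 1869 tags (1550.0-fold, 278 to 61254), the ventral homeobox gene ventx1.1 442-fold (189 to 1361) and the sodium pump subunit atp1b2 572-fold from 3 tags (195 to 2776). The largest falls were those of LOC733731 (119-fold, 97.2 to 147), hadhb (158-fold, 95.3 to 282), the glutathione transferase mgst1 (118-fold, 68.6 to 222), fam3c (80.8-fold), n6amt2 (48.4-fold), LOC733945 (67.3-fold), mapk8 (26.3-fold), the sugar epimerase galm (31.2-fold) and the splicing factor esrp1 (25.1-fold).

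Among the list members, the endoderm genes mix1 and sox17b.1 rose 46.4-fold (25.1 to 97.4) and 46.2-fold (31.1 to 71.6), sox17a 64.0-fold (27.2 to 198) and eomes at least 167-fold. In the mesoderm the presomitic mesoderm factor msgn1 rose at least 59.7-fold and the posterior gene cdx4 at least 71.9-fold. In the organizer gsc rose 26.1-fold (16.1 to 45.1), the Wnt antagonist frzb at least 194-fold, the kinase gene pkdcc at least 157-fold, and chrd 130-fold from 3 tags (44.4 to 635). The ventral ligand bmp4 rose 32.0-fold, and in the ectoderm tfap2a rose 238-fold, foxi4.2 216-fold and the neural gene foxd4l1.1 81.1-fold, while id2 fell 5.35-fold and krt18 3.93-fold.

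The remaining lists showed mixed changes. Of the Nodal ligand list cer1 and gdf1 (2.69-fold) rose and tdgf1 fell 2.06-fold, less in its highest region alone (median 1.32, percentile 87.4). The transduction list had a median of 0.08, below 0 with the other scalings, with smad2 lower 4.65-fold, the corepressor drap1 lower 2.26-fold (not with a pseudocount of 5) and tcf7l1 higher 2.46-fold (not with median of ratios). Of 14 maternal genes 5 fell and 1 rose (median -0.61, matched lists -0.64 to 0.97), with btg4, which drives mRNA deadenylation, down 13.4-fold, cpeb1, which controls polyadenylation, down 5.56-fold and vegt up 2.95-fold. Among the maternal falls, zp2 was above 0 in its highest region alone. The pluripotency list rose in 4 of 7 genes (median 1.06), klf17 by 27.7-fold and sall1 by 7.36-fold, and the housekeeping median was 0.84 (percentile 98.8). Among the pluripotency rises, sall4 was below 0 in its highest region alone. Ribosomal protein genes had a median of -0.32 (14 lower, 7 higher). The Hox gene hoxd1 rose 206-fold from 3 tags (70.2 to 1001), and of the later cell types alb and the tubulin gene tubb2b had log2 ratios of 0.89 and 0.97.

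Genes with a Smad2/3 site of stage 10.5 rose more often than others at that stage. The 270 comparable genes had a median log2 of 1.15 from stage 9 to 10.5 (matched lists 0.09 to 0.47), and 145 of them (53.7%) were at least 2-fold higher, against 27.6% of the genes without a site. The 210 comparable from stage 8 to 9 had a median of -0.45 (percentile 40.3).

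**Figure D5:**
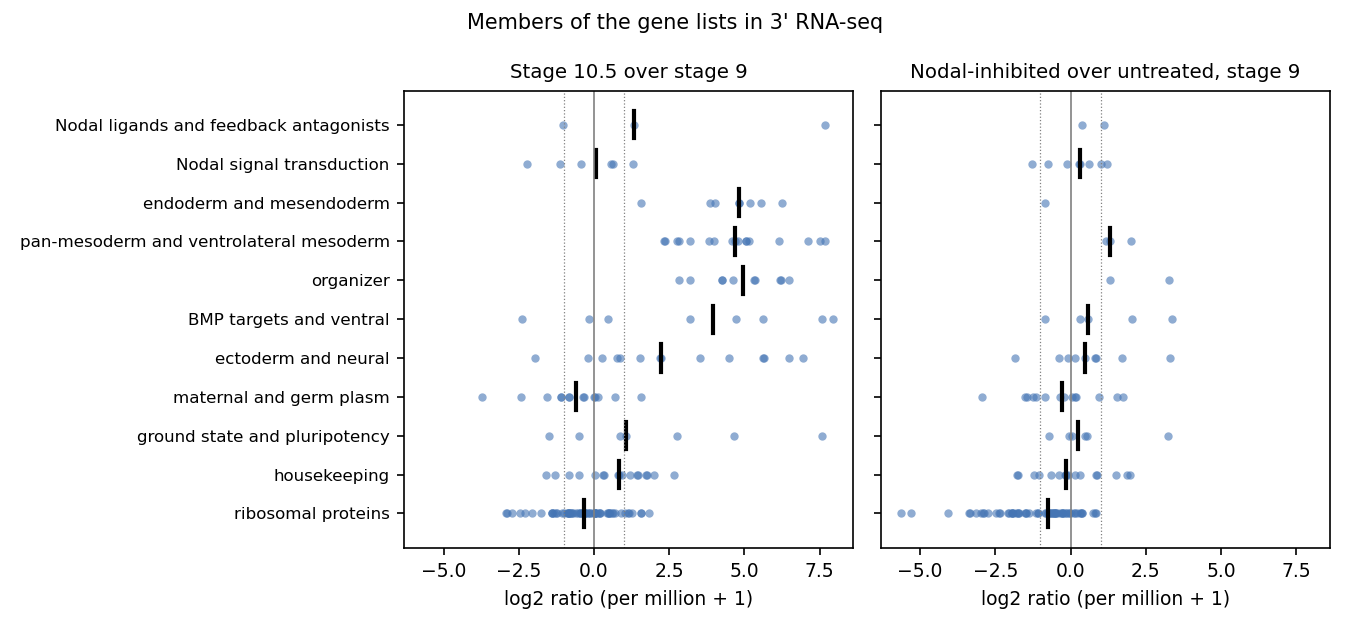
Log2 ratios of the members of the fixed gene lists from stage 9 to 10.5 and under Nodal inhibition at stage 9, with list medians as bars. Germ layer lists lie above 0 from stage 9 to 10.5 and ribosomal proteins below 0 under inhibition with each scaling, while the transduction median from stage 9 to 10.5 lies below 0 with the other scalings.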

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

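A large part of the RNA tags lay in regions that name no gene and stayed outside the gene comparisons. They made up 32.6% of the tags at stage 8, 29.1% at stage 9, 29.5% at stage 10.5 and 30.5% under Nodal inhibition. The table holds 5252, 3841, 4383 and 4100 such regions with at least 10 CPM (library-scaled tags) in these libraries. Counted as single regions, they changed more often than named genes, whose regions were summed. Of 5155 unnamed regions compared under inhibition, 1217 were at least 2-fold lower and 1428 higher, while 1794 of 4819 named genes changed in either direction. From stage 8 to 9 it was 2331 and 848 of 6046 (1789 of 4953 named genes), and from stage 9 to 10.5 it was 1454 and 2092 of 5634 (2334 of 5045 named genes). These regions were not assigned to genes here, and no explanation of their content was tested.

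The names of all 11314 peaks in the list labelled H3K27ac at stage 9 start with a stage 8 prefix, while the header of that list names stage 9. The other stage 9 lists have no such names. Only 1 of its intervals is identical to one of the stage 8 list, so the list is not a copy of that one. This cannot show which stage its reads came from, and the list was used as stage 9 by its header.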

How the results depend on the processing

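The 364 results were recomputed under alternative settings, which gave 2768 values, 2160 of them from the plan and 608 chosen after seeing the data. Of these 2599 kept direction and size. Among values that answer a comparison 64 moved and 2 became stronger, and these are printed here. For single genes 65 values dropped below and 35 rose above the 2-fold threshold, and 3 values of genes changed 2-fold in the main setting changed sign. No paired analysis was possible because each group had 1 sample. Unless a cause is given, the cause was not tested. Depth limits the falls that can be seen: with few tags in the lower library only a bound can be given.

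Kept marks are given as untreated H3K27ac peaks overlapped under Nodal inhibition (percent), untreated H3K27ac peaks with Smad2/3 overlapped under Nodal inhibition (percent), untreated H3K27ac peaks without Smad2/3 overlapped under Nodal inhibition (percent), untreated H3K4me1 peaks overlapped under Nodal inhibition (percent), untreated H3K4me1 peaks with Smad2/3 overlapped under Nodal inhibition (percent) and untreated H3K4me1 peaks without Smad2/3 overlapped under Nodal inhibition (percent). The main values were 52.9, 26.1, 53.0, 53.6, 38.2 and 53.7. Asking for at least 50% of the untreated peak gave 40.7, 10.9, 40.9, 45.3, 23.6 and 45.3, and 42.7 (H3K27ac) and 41.8 (H3K4me1) near lower genes, lower by construction. The upper part by score gave 41.0 and 41.1 (all, without Smad2/3) for H3K27ac and 56.2 and 56.2 for H3K4me1. Lists of equal covered length gave 46.2 and 46.3, and 66.0 and 66.0. Stage 10.5 Smad2/3 peaks, chosen after seeing the data, gave 84.2 with and 51.4 without Smad2/3 for H3K27ac and 81.3 and 52.9 for H3K4me1, so this comparison depends on the Smad2/3 list.

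For marks at Smad2/3 sites the values are points above moved sites, such as H3K4me1 stage 10.5 at Smad2/3 stage 10.5 sites: excess over shifted positions (percentage points), H3K27ac stage 10.5 at Smad2/3 stage 10.5 sites: excess over shifted positions (percentage points), H3K27ac stage 9 at Smad2/3 stage 9 sites: excess over shifted positions (percentage points) and H3K27ac stage 9 at new Smad2/3 stage 10.5 sites: excess over shifted positions (percentage points). Asking for 50% of the Smad2/3 peak moved H3K4me1 at stage 10.5 from 82.9 to 84.1. Shifts of 200 to 500 kb gave 87.6 for it and 84.9 for H3K27ac. The upper part of the Smad2/3 list gave 4.08 (H3K4me1), 3.70 (H3K27ac) and 6.02 (H3K4me3) at stage 9, 3.68 for stage 8 H3K27ac at sites new at stage 9, and 71.5 (H3K4me1) and 69.8 (H3K27ac) for stage 9 marks at sites new at stage 10.5. The upper part of the mark list gave 1.47 for H3K4me3 at stage 9, 79.4 (H3K4me1) and 15.8 (H3K4me3) at stage 10.5, 1.55 for stage 8 H3K4me3 at new stage 9 sites, and 52.1 (H3K4me1) and 49.5 (H3K27ac) for stage 9 marks at new stage 10.5 sites, fewer marks by construction.

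Between stages the upper part by score gave 0% overlap of Smad2/3 peaks of stages 8 and 9 in both directions. For H3K4me1 stage 9 covered length also covered at stage 10.5 (percent) it gave 80.1, and from stage 8 to 9 it gave 91.7 (H3K4me1), 69.3 (H3K27ac), 56.9 (H3K4me3) and 43.7 (H3K27me3). Promoter shares at stage 10.5 became 19.8, 22.8, 46.6 and 0% for the same marks, and with a window of 5 kb 20.5, 22.5, 42.2 and 8.94%, higher by construction. Smad2/3 lists of equal length moved the share of stage 10.5 peaks found at stage 8 from 1.37 to 4.83%. Without the recurrent loci, chosen after seeing the data, Smad2/3 overlap of stages 8 and 10.5 was 0% in both directions, and shared H3K27me3 length was 0% from stage 8 to 9 and 48.6% from stage 9 to 10.5. The H3K27me3 values are lower by construction, since these loci were chosen as called for that mark at every stage.

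For transcripts, TMM moved the genes lower and higher from stage 8 to 9 from 1428 and 361 to 716 and 850, and stage 9 over stage 8: housekeeping median log2 from -0.52 to -0.013, which is below the range of matched lists with TMM only. Median of ratios gave 692 and 876. A minimum of 50 CPM gave 584 higher under inhibition, 842 lower from stage 8 to 9 and 899 higher from stage 9 to 10.5, with fewer genes compared (3114, 3331 and 3314). With no minimum the BMP median under inhibition was 0.98 in place of 0.58. With stage 8 as reference, chosen after seeing the data, 1459 genes were lower and 586 higher in the inhibited library. By the highest region alone, stk11 from stage 8 to 9 went from -1.17 to 0.72, and stage 10.5 over stage 9: sall4 log2 from 1.06 to -0.25 and zp2 from -1.09 to 0.38.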

Other observations

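Of the tests in this part, those of scaling and of the highest scores were set before their results were seen, and all others were chosen after the pattern was seen. By the start of gastrulation the called Smad2/3 sites lay at elements that carried H3K4me1 (95.7%) and H3K27ac (92.8%), near 39 of 57 genes of the Nodal, endoderm, mesoderm and organizer lists. Most of these elements already had H3K4me1 (74.8%) or H3K27ac (66.6%) at stage 9, when genes such as t, eomes and cer1 still had at most 1 tag. The same genes then rose by stage 10.5, cer1 at least 453-fold and eomes at least 167-fold. Whether Smad2/3 already lay at these elements at stage 9 stays open, because the stage 9 list shared no peak with that of stage 10.5.

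Of the 1024 later sites 684 carried H3K27ac in untreated stage 9 embryos, and with Nodal receptors blocked 523 of these still did and 161 did not, while 84 others carried it only in the inhibited embryos. The stage of that untreated list rests on its header. The highest-score sites of gsc, foxa4, gata4 and not kept both marks, while those of lefty and snai1 and the neighbourhood of nodal1 had no H3K27ac in inhibited embryos. Other sites, such as those of cer1, chrd and otx2, had H3K27ac only in inhibited embryos. Among the 39 list genes it lay at 23 sites in untreated and 22 in inhibited embryos. The inhibited arm differs from the untreated arm in aligner and adapters, and rests on 1 library of each kind. A repeat with both arms made and aligned alike, with at least 3 pools each, would separate these causes.

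The first pattern was that genes that switch on by stage 10.5 were higher under inhibition: of 216 such zygotic genes 90 (41.7%) were at least 2-fold higher and 6 lower (median log2 0.72, matched lists 0.14 to 0.48). If the inhibited embryos were further past the onset of zygotic transcription, genes that fall by stage 10.5 should be lower, and the 342 falling genes had a median of -0.29 (matched lists 0.10 to 0.36), which is consistent with that. Scaling of the libraries is argued against only in part: with median of ratios 86 genes were still at least 2-fold higher. The median of 0.73 with that scaling (matched lists 0.00 to 0.31) cannot test this, and the 0.72 has the same limit. Members at the median, such as eomes, had 0 tags untreated and 3 inhibited, so their ratio is set by the pseudocount. The 6 lower genes say little because many members are too near 0 at stage 9 to be called lower. Release of genes that Smad2/3 holds down is left open: 38.1% (26.1 to 51.2%) of the 63 zygotic genes with a stage 10.5 site were higher against 43.1% of the 153 without, which meets the bound set against it, but an interval this wide cannot exclude a modest difference. The set is not uniform, since of its 28 members in the Nodal, endoderm, mesoderm and organizer lists 6 were higher (median 0.18, percentile 30.8) and of its 11 other BMP and ectoderm members 9 were (median 1.37, percentile 99.8), but the members are few and mostly at low counts, so whether Nodal loss moved either group stays open.

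The second pattern was the very large falls of genes with no known tie to Nodal, such as hadhb, gyg1 and mapk8. If the untreated stage 9 library stood apart, few of the fallen genes should lie below the other stages too, and 26.6% (23.6 to 29.8%) of the 805 were at least 2-fold below both stage 8 and stage 10.5. That is above the 8.49% of all genes, a contrast raised by choosing the genes on this ratio. The untreated value lay at least 2-fold above both stages in 22.5%, against 4.69% of all genes, and the same choice raises this share. The part of the falls that the stage 9 library may account for therefore cannot be sized here. Lower ribosomal protein transcripts under inhibition did not rest on the stage 9 library alone, since their median lay below the matched range against stage 8 (-0.50, -0.16 with median of ratios and -0.11 with TMM) and against stage 10.5 (-0.93, -0.83 and -0.78), though its size against stage 8 depends on the scaling. Against stage 8 and stage 9 alike 526 genes were lower and 349 higher, which cannot separate an effect of inhibition from a deviation of the inhibited library that both comparisons share.

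The third pattern was that most stage 9 Smad2/3 sites lacked marks, though H3K4me3 was a few points above moved sites (4.86% against 1.03%). GC-rich fragments in the library could give such peaks, and of the 88 movable sites with GC under 50% 18.2% overlapped H3K4me1 (4.13% when moved, and less in every draw) against 4.91% of the 591 movable others, above moved sites but short of the 20 points that would have pointed to GC, so this is left open. True sites only among the highest scores are left open, since of the 73 movable among the 100 best 17.8% overlapped H3K4me1, against 97.8% of 92 at stage 10.5. That value equals the highest draw of moved sites (17.8%) and so meets the bound set against it, which was a poor bound because so few sites leave the draws wide. Binding sites of stage 9 that differ from those of stage 10.5 are also left open, with 3 of 57 list genes near one (upper bound of 95% of random draws 5).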
